A study of Homo sapiens with 4 samples.

How the data were processed

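RNA-seq was deposited for 4 libraries of TamR MCF-7 cells, 2 with a scrambled shRNA and 2 with shRNA against EZH2, made per the labels' protocols from 1 ug of total RNA with an Illumina TruSeq RNA v2 kit, which does not mark strand. The authors deposited raw read counts per gene, with exon coordinates and exon length, for 26364 genes. Per the submitters' processing notes, CASAVA, TopHat2 2.0.10, featureCounts and edgeR were used with the hg19 genome; the options of each are not given in the sources used here. Because strand is not marked, reads of overlapping and antisense genes cannot be told apart. Of the deposited gene symbols, 28 had been turned into dates, 25 of them tested, and 6050 genes had 0 counts in all libraries. Total counts ranged from 38686093 to 49319665.

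Groups and replicate numbers came from the sample titles. Chi-square per degree of freedom between libraries of a group was 198 for shCtrl and 165 for shEZH2, above counting noise, so no pair was treated as repeat deposits of a single library. This does not show that the libraries are independent replicates. The test, the gene lists, the rule for naming genes and the alternatives were fixed before the data were examined, except where said otherwise.

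The main test was edgeR 4.0.16 (R 4.3.3) with TMM scaling, filterByExpr by group, and the quasi-likelihood F test of shEZH2 against shCtrl with no covariate, on 15187 genes, with Benjamini-Hochberg adjusted p under 0.05. Residual degrees of freedom were 2. The SE of a log2 fold change was its size divided by the square root of F. Levels are CPM with TMM scaling, as mean ± SD (n = 2). Log2 ratios within a replicate number were differences of log2 CPM with a prior count of 2. Simulated counts had means set per replicate number and the dispersion of a fit with the number as a covariate. On them, the main test recovered 0% of genes changed 1.5-fold, 2-fold or 4-fold over 15048 genes. The fit with the number as a covariate recovered 37.6%, 84.2% and 99.7%, with 5.03% false calls. The counts were drawn from that same model, with differences between numbers shared by the groups. Recovery by both fits is therefore built in and does not test either fit on the deposited data.

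For lists, 36 were fixed, with 1089 entries, of which 1074 matched by symbol, 2 by another name and 13, all mitochondrial, did not match. The 33 with at least 5 tested members were tested with limma 3.58.1 camera on log2 CPM, two-sided, with a preset correlation of 0.01, and beside it with an estimated correlation and with fry. In simulation, camera called the moved list in 5 of 5 runs and 0 of 50 unmoved lists, but simulated genes were independent, so correlation between genes was not tested. Some genes are in more than a single list.

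Named genes were EZH2, EZH1, GREB1 and ESR1 always, the last pair because published work on this model is known to concern them. Genes past the threshold with separate groups, a mean of at least 2 CPM and a named symbol were to be given as the 10 highest and 10 lowest, but 0 qualified. After that was seen, the same rule without its adjusted p was used to take 20 genes by size. For each list, up to 4 members with the smallest p and a mean of at least 1 CPM were eligible, called or not. The gene with the largest count was also named.

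Fits that were run beside the main fit used RLE, library size or upper-quartile scaling, DESeq2 1.42.0, limma-voom, edgeR's likelihood ratio test, no filter, a filter of at least 1 CPM, a gene length correction, a log2 fold change of at least 1, each library left out in turn, and the replicate number as a block, alone and with the length correction. Added after seeing the data were edgeR's camera on z-scores, the block combined with each other choice apart from the length correction, and corrections for GC content and depth. The block was planned as an alternative because the labels do not say that a number marks a shared day or culture. It called many genes where the main fit called none, and the main fit was kept as the main result. Figures were drawn with matplotlib 3.10.9.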

Results

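RNA was sequenced from TamR MCF-7 cells, a tamoxifen-resistant derivative of the estrogen receptor positive breast cancer line MCF-7, grown in 100 nM 4-hydroxytamoxifen. Cells stably carrying an shRNA against EZH2 (shEZH2) were compared with cells carrying a scrambled shRNA (shCtrl), with 2 libraries per group. The comparison asks which transcripts differ when EZH2, the catalytic subunit of Polycomb repressive complex 2 and a histone H3 lysine 27 methyltransferase, is depleted in resistant cells. Total counts were 40427445 and 49319665 in shCtrl replicates 1 and 2, and 38686093 and 48675227 in shEZH2 replicates 1 and 2. The labels do not say whether libraries of a group came from separate cultures. The p-values of single genes therefore measure only the spread between these libraries, which may be technical. Of 26364 genes listed, 15187 passed the low-count filter and were tested.

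EZH2 itself (hg19 chromosome 7, 148504464 to 148581441) had 894 and 963 counts in the shCtrl libraries and 311 and 293 in the shEZH2 libraries. Its level was 20.8 ± 1.36 CPM in shCtrl and 7.01 ± 1.18 CPM in shEZH2 (SD, n = 2 each), a log2 fold change of -1.57 ± 0.26 (SE). The log2 ratio of shEZH2 to shCtrl was -1.47 between the libraries numbered 1 and -1.67 between those numbered 2. The unadjusted p of edgeR's quasi-likelihood test across all 15187 genes was 0.0016, and the Benjamini-Hochberg adjusted p from edgeR was 0.999531. Adjusted over the list alone, EZH2 was the only one of 13 tested Polycomb repressive complex 2 genes to pass. EZH1, the paralogous methyltransferase (chromosome 17, 40852293 to 40897071), had a log2 fold change of 0.21 ± 0.25 (SE).

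**Figure D1:**
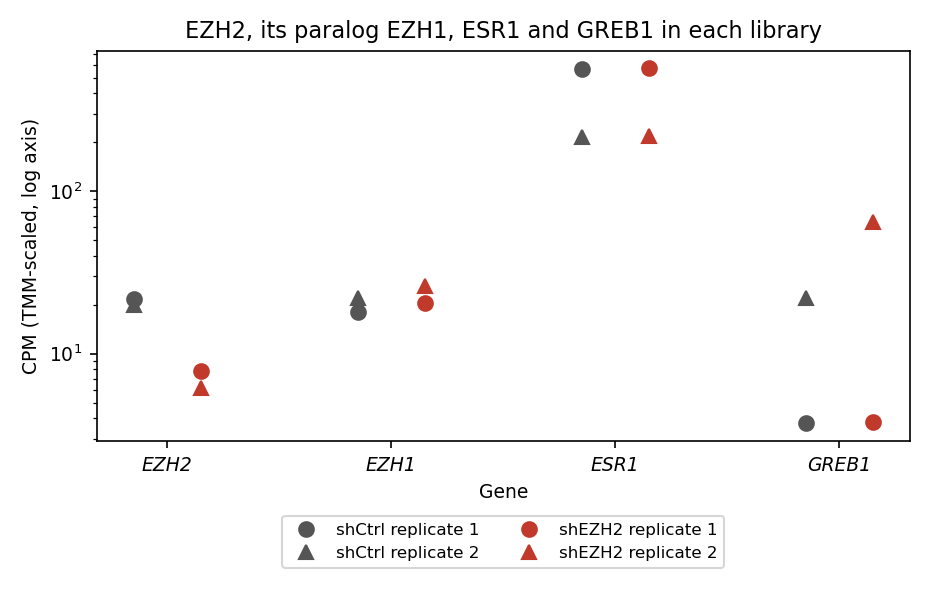
CPM after TMM scaling, on a log axis, of 4 genes fixed before the data were examined, with a point per library, shCtrl in grey and shEZH2 in red, circles for replicate 1 and triangles for replicate 2. EZH2 was lower in both shEZH2 libraries, ESR1 and GREB1 differed between replicate numbers, and GREB1 was higher in shEZH2 in replicate 2 only.

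The estrogen receptor gene ESR1 (chromosome 6, 152011631 to 152424408) had a log2 fold change of 0.01 ± 0.63 (SE). Its within-number log2 ratios were 0.01 and 0.03, while its level was 566 and 569 CPM in the replicate 1 libraries and 216 and 219 CPM in the replicate 2 libraries. GREB1, an estrogen-induced coregulator of the receptor (chromosome 2, 11674242 to 11782912), had 153 and 1076 counts in shCtrl and 150 and 3061 in shEZH2. Its log2 fold change was 1.40 ± 1.38 (SE), with ratios of 0.02 in replicate 1 and 1.54 in replicate 2. The difference therefore rested on a single pair of libraries, and without shEZH2 replicate 2 the fold change was -1.78. That fit set shEZH2 replicate 1 (3.78 CPM) against shCtrl replicates 1 and 2 (3.72 and 22.2 CPM). It therefore mixes group with replicate number and does not show a reversed effect of the knockdown.

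No gene passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, where the smallest adjusted p was 0.999531. At an unadjusted p under 0.05 there were 682 genes, 421 higher and 261 lower in shEZH2, against 759 expected by chance. DESeq2 called 69 genes, edgeR's likelihood ratio test 48 and limma-voom 0. Replicate number was the main axis of variation: the first principal component, with 60.5% of the variance, separated the libraries by number, and the second, with 29.97%, separated shEZH2 from shCtrl. Correlations of log2 CPM across genes were 0.986 and 0.983 between libraries of the same number and 0.971 and 0.974 within groups. Counts were also simulated with differences between numbers set as shared by the groups. On them the same test recovered 0% of genes changed 4-fold, which follows from that setting. The absence of calls does not show an absence of changes. That test had no term for replicate number, so differences between numbers stayed in its residual spread. With the number as a block, edgeR's quasi-likelihood test called 1399 genes, 779 higher and 620 lower in shEZH2. The labels do not say what a number marks, so that count rests on an unstated pairing.

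The rule for naming genes past the threshold therefore named none. The 20 genes given next were taken by size after that was seen, as the 10 highest and 10 lowest log2 fold changes among genes with separate groups and a mean of at least 2 CPM. None of them passed the main test, which had no term for replicate number. All 20 passed edgeR's quasi-likelihood test with the number as a block, which rests on an unstated pairing. They were chosen on these same data, and a ranking by size favours genes with large chance differences. The interferon-induced IFI27 (4.10 ± 0.94), KRT4 (3.55 ± 0.95), the TNF receptor family member TNFRSF19 (3.40 ± 0.32), SYBU (3.33 ± 0.60), NCAM2 (3.17 ± 1.22), TRIM29 (2.77 ± 0.39), CEACAM6 (2.71 ± 0.91), AMTN (2.68 ± 0.34), the ephrin receptor EPHA3 (2.60 ± 0.37) and the uroplakin UPK2 (2.59 ± 0.73) were highest in log2 fold change (± SE). DEFB1 (-3.29 ± 1.41), ITIH2 (-2.77 ± 0.44), the collagen cross-linking enzyme LOX (-2.40 ± 1.06), spermidine synthase SRM (-2.32 ± 0.23), ATP8B4 (-2.20 ± 0.46), GRAMD2 (-2.18 ± 0.47), ZMAT4 (-2.07 ± 0.55), STARD8 (-2.03 ± 0.58), MGP (-1.86 ± 0.45) and the integrin ITGB6 (-1.82 ± 0.46) were lowest. KRT4 had ratios of 1.40 and 5.31, and MGP -2.74 and -0.94, while TNFRSF19 (3.41 and 3.32) and SRM (-2.34 and -2.29) hardly differed between numbers. CEACAM6, the keratins, the histones and the class I and II HLA genes share sequence with near-identical family members, so their counts are uncertain where reads could be split.

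**Figure D2:**
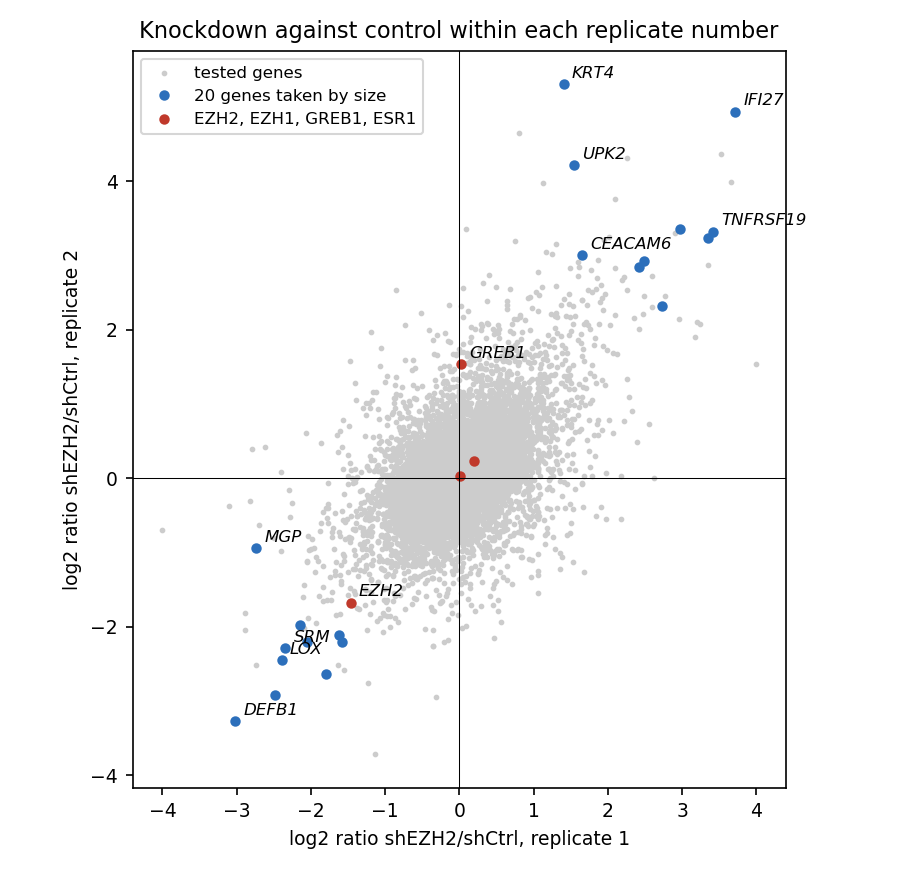
Log2 ratio of shEZH2 to shCtrl between the replicate 1 libraries (x axis) and the replicate 2 libraries (y axis), with a grey point per tested gene, the 20 genes taken by size in blue and EZH2, EZH1, GREB1 and ESR1 in red. Across genes, which are not independent replicates, the ratios correlated with r = 0.51 and rho = 0.44.

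Gene lists fixed before the data were examined were tested with camera, which compares each list with all other tested genes. With a preset inter-gene correlation of 0.01, 13 of 33 lists passed an adjusted p of 0.05, 7 higher and 6 lower in shEZH2. That p rests on the spread across genes, taken as nearly independent, and does not measure the spread between libraries. Its small values, here and below, do not count as evidence over replicates. With an estimated correlation none passed, and the smallest adjusted p = 0.49. All 13 list calls were therefore made only with the preset correlation. The test with an estimated correlation uses the 2 residual degrees of freedom, so hardly any list could pass with so few libraries. The loss of the calls, here and below, therefore decides little. It does not by itself show that list members were correlated. Over all genes tested, 0 members of any list passed in edgeR's quasi-likelihood test, and where no count adjusted over the list alone is given it was 0. A fit without a library leaves the replicate numbers unequal between the groups. A list call lost in such a fit, here and below, can therefore follow number as well as knockdown. Of the 13, 3 (interferon response, antigen presentation and mitosis) were kept without each of the 4 libraries in turn.

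The interferon response list rose as a set (camera adjusted p = 5.7e-21, and adjusted p = 0.49 with an estimated correlation). Of 43 tested members, 38 were higher in shEZH2 within both replicate numbers and 1 was lower, with list medians of 0.65 and 1.42 in log2 ratio. Adjusted over the list alone, 6 members passed, against 0 over all genes tested. The antiviral genes SAMD9 (4.45 ± 0.70), OAS2 (4.03 ± 0.61), IFI44L (3.25 ± 0.66) and IFIT1 (2.33 ± 0.41) had the smallest p in log2 fold change (± SE). SAMD9, OAS2 and IFI44L exceeded some of the 10 highest genes above but were not among them. They therefore had a mean under 2 CPM or overlapping groups. The antigen presentation list rose as well (camera adjusted p = 1.1e-07, and adjusted p = 0.49 with an estimated correlation). In that list 17 of 19 members were higher within both numbers, with medians of 0.58 and 0.78, and none passed adjusted over the list alone. HLA-DRB1 had a log2 fold change of 1.30 ± 0.41, HLA-B 1.14 ± 0.25, HLA-C 0.87 ± 0.29 and the peptide-trimming ERAP1 0.75 ± 0.27. Markers of leukocytes and endothelium did not pass as a list (camera adjusted p = 0.67 over 5 tested members).

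Genes of mitosis fell as a set (camera adjusted p = 4.9e-13, and adjusted p = 0.49 with an estimated correlation), and all 38 tested members were lower in shEZH2 within both numbers. The list medians were -0.34 and -0.67, and none passed adjusted over the list alone. The kinetochore motor CENPE had a log2 fold change of -1.46 ± 0.37, NDC80 -0.69 ± 0.24, the kinase AURKB -0.68 ± 0.22 and KIF2C -0.67 ± 0.21. The list of E2F targets and DNA replication genes fell too (camera adjusted p = 8.2e-07, and adjusted p = 0.69 with an estimated correlation), with 20 of 37 members lower within both numbers. Its medians were -0.75 in replicate 1 and -0.02 in replicate 2, and without shCtrl replicate 1 the test pointed the other way. That fit leaves shCtrl with replicate 2 only. The list was lower in replicate 2 than in replicate 1 (0 called higher and 19 lower of 37), so the direction can follow number. GINS1 (-0.71 ± 0.33), RFC4 (-0.59 ± 0.22), RFC3 (-0.56 ± 0.21) and MCM6 (-0.54 ± 0.27) had the smallest p, and none passed adjusted over the list alone. The p53 target list rose (camera adjusted p = 0.0017, and adjusted p = 0.73 with an estimated correlation), with 21 of 30 members higher and 6 lower within both numbers. BTG2 had a log2 fold change of 1.25 ± 0.26, TP53INP1 1.12 ± 0.28, FDXR 0.69 ± 0.25 and PHLDA3 0.49 ± 0.20. That call was lost without shCtrl replicate 1 and without shEZH2 replicate 2. The list was higher in replicate 2 than in replicate 1 (18 called higher and 0 lower of 30), so both losses can follow number. Histone genes rose as a list (camera adjusted p = 1.6e-06, and adjusted p = 0.49 with an estimated correlation), and 11 of 12 were higher within both numbers. HIST1H2AC (1.5003 ± 0.32), HIST1H2BD (1.20 ± 0.35) and HIST2H2BE (1.03 ± 0.33) were higher and HIST2H2AC (-1.12 ± 0.33) was lower. Adjusted over the list alone 2 members passed, and the list call was lost without shEZH2 replicate 1 (camera adjusted p = 0.079).

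The luminal epithelial list rose (camera adjusted p = 0.0017, and adjusted p = 0.49 with an estimated correlation), with 17 of 29 members higher and 2 lower within both numbers. The epithelial transcription factor ELF3 had a log2 fold change of 1.98 ± 0.30, GATA3 1.58 ± 0.61, the tight junction gene CLDN4 1.09 ± 0.25 and E-cadherin CDH1 0.66 ± 0.29. Adjusted over the list alone 1 member passed, and the call was lost without shCtrl replicate 2 (camera adjusted p = 0.11) and without shEZH2 replicate 1 (0.070). The basal list also rose (camera adjusted p = 0.044, and adjusted p = 0.49 with an estimated correlation), with 13 of 21 members higher and 5 lower. TRIM29 (2.77 ± 0.39), LAMB3 (1.29 ± 0.29) and CAV2 (0.89 ± 0.28) were higher and EGFR (-0.62 ± 0.28) was lower. Adjusted over the list alone 1 member passed, and the call was lost without shCtrl replicate 1 (camera adjusted p = 0.48) and without shEZH2 replicate 2 (0.52). Genes repressed by estrogen rose as a list (camera adjusted p = 0.049, and adjusted p = 0.49 with an estimated correlation). BCAS1 (1.65 ± 0.24), TP53INP1 and EFNA1 (0.62 ± 0.20) were higher, while the hypoxia-inducible factor EPAS1 (-1.47 ± 0.24) was lower, and 2 members passed adjusted over the list alone. The call was lost without shCtrl replicate 1 (camera adjusted p = 0.16), shCtrl replicate 2 (0.12) or shEZH2 replicate 1 (0.21). Genes induced by estrogen did not pass (camera adjusted p = 0.49), with 13 of 46 members higher and 14 lower within both numbers. Their median log2 fold change was 0.03 although the test's direction was lower. The receptor kinase RET (-0.95 ± 0.21), RERG (-1.42 ± 0.38) and RARA (-0.54 ± 0.22) were lower and PKIB (0.55 ± 0.21) was higher.

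The receptor tyrosine kinase list fell (camera adjusted p = 0.040, and adjusted p = 0.49 with an estimated correlation), with 20 of 38 members lower and 11 higher within both numbers. The feedback inhibitor SPRY4 had a log2 fold change of -1.49 ± 0.23, the phosphatase DUSP5 -1.20 ± 0.33 and IER3 -0.86 ± 0.28, and 1 member passed adjusted over the list alone. The call was lost without shCtrl replicate 1 (camera adjusted p = 0.11), shCtrl replicate 2 (0.17) or shEZH2 replicate 1 (0.40). The WNT, NOTCH and hedgehog list fell (camera adjusted p = 0.034, and adjusted p = 0.49 with an estimated correlation), with 14 of 28 members lower and 6 higher. WNT5A (-1.41 ± 0.38), the NOTCH ligand DLL1 (-1.39 ± 0.55), the WNT receptor FZD8 (-1.04 ± 0.27) and HEY1 (-0.89 ± 0.34) had the smallest p. The call was lost without shCtrl replicate 1 (camera adjusted p = 0.48), shEZH2 replicate 1 (0.12) or shEZH2 replicate 2 (0.27). Hypoxia and glycolysis genes fell as a list (camera adjusted p = 0.049, and adjusted p = 0.49 with an estimated correlation), with 15 of 30 members lower and 6 higher. Carbonic anhydrase CA9 (-1.41 ± 0.73), lactate dehydrogenase LDHA (-0.87 ± 0.32), PDK1 (-0.87 ± 0.42) and PFKP (-0.34 ± 0.20) had the smallest p. The DNA methylation list fell (camera adjusted p = 0.046, and adjusted p = 0.49 with an estimated correlation), with 8 of 14 members lower and 2 higher. The maintenance methyltransferase DNMT1 had a log2 fold change of -0.57 ± 0.21, HELLS -0.54 ± 0.28 and MBD3 -0.39 ± 0.21. The last 2 list calls were lost without any of the 4 libraries, with camera adjusted p from 0.084 to 0.25 for hypoxia and from 0.099 to 0.26 for DNA methylation.

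Lists tied to Polycomb silencing did not pass. Bivalent developmental regulators had a camera adjusted p of 0.10, with 10 of 40 members higher and 22 lower within both numbers. SOX2 (1.10 ± 0.38) and SOX9 (1.00 ± 0.23) were higher, and EN2 (-1.35 ± 0.36) and SIX2 (-1.32 ± 0.51) were lower. Genes reported to be repressed by EZH2 in cancer had 9 of 22 members higher and 8 lower (camera adjusted p = 0.996), with IGFBP3 at 2.07 ± 0.93 and overlapping groups. HOX genes had a camera adjusted p of 0.22, Polycomb repressive complex 2 genes 0.22 and Polycomb repressive complex 1 genes with the H3K27 demethylases 0.62. In the last list PCGF6 (-0.68 ± 0.24) and CBX2 (-0.60 ± 0.24) were lower.

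Of the other lists, cholesterol synthesis came nearest to the threshold (camera adjusted p = 0.052), with 16 of 24 members higher within both numbers and INSIG1 at 0.57 ± 0.20. The camera adjusted p was 0.12 for mesenchymal genes, 0.21 for adhesion and matrix, 0.22 for ribosomal proteins and 0.34 for the BCL2 family and apoptosis, in which BCL2L1 was 0.75 ± 0.20. It was 0.58 for neuronal genes, where CNTNAP2 (1.91 ± 0.30) and MAP2 (2.16 ± 0.59) were higher and 1 member passed adjusted over the list alone. It was 0.62 for NF-kB genes and 0.67 for fatty acid synthesis, 0.95 for immediate early genes, and 0.996 for cyclins with CDK inhibitors, receptor cofactors, the unfolded protein and integrated stress response, and drug metabolism, in which ALDH3A1 was 1.74 ± 0.35. Fibroblast markers and cancer-testis antigens had 3 tested members each and mitochondrial transcripts 0, too few to test. Of the other-cell markers, CD68 was -0.95 ± 0.39, COL1A1 -0.56 ± 0.28, LYZ 0.35 ± 0.40 and COL3A1 0.19 ± 0.27. EEF1A1 had the largest count in each library, with 1.06% and 1.82% of counts in shCtrl and 0.996% and 1.82% in shEZH2.

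**Figure D3:**
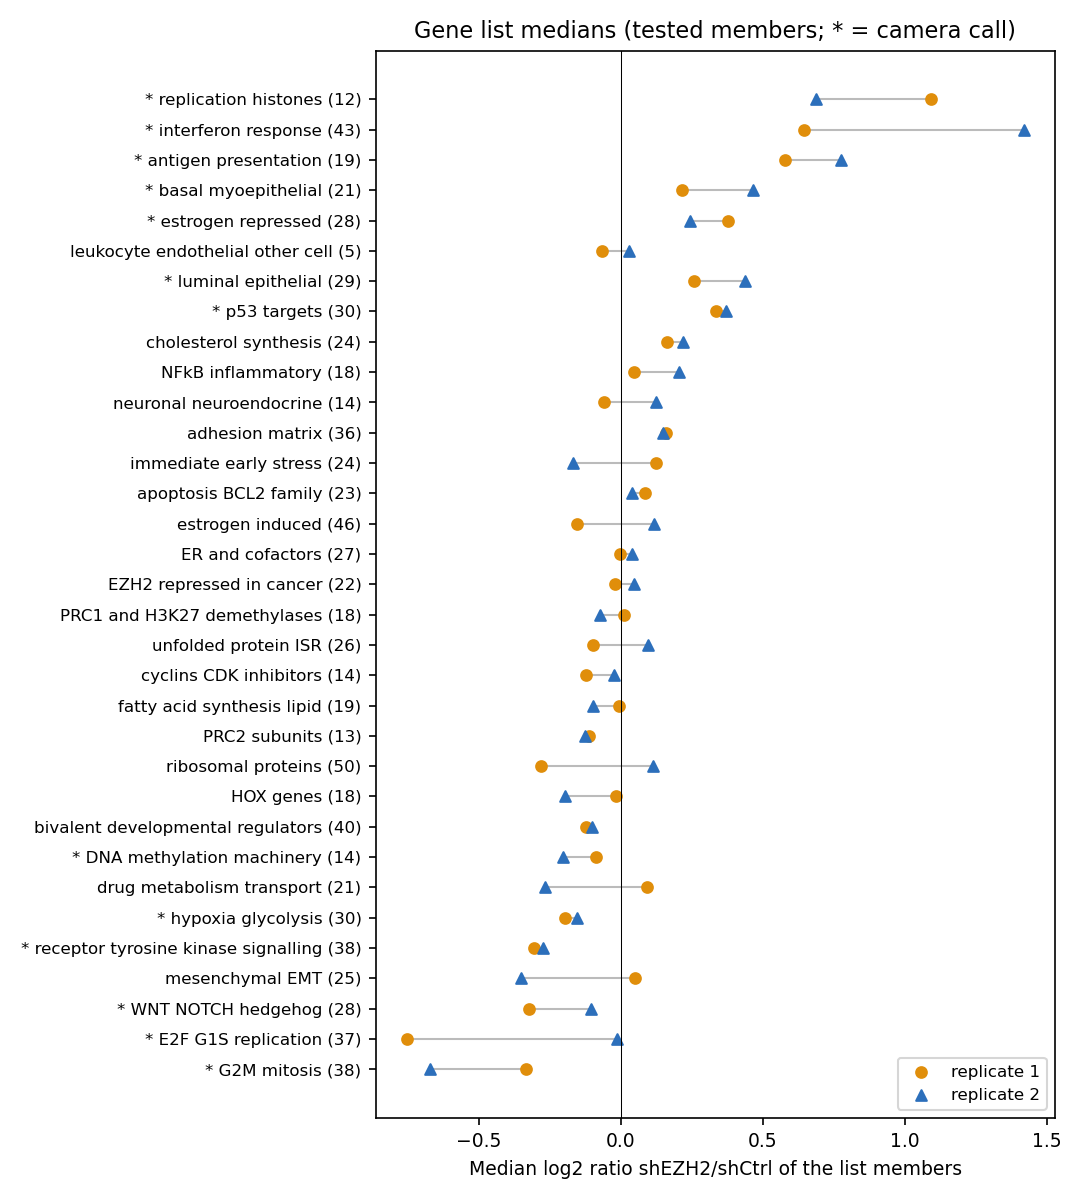
Median log2 ratio of shEZH2 to shCtrl over the tested members of each list, between replicate 1 libraries (circles) and replicate 2 libraries (triangles), with the number of tested members in parentheses. A star marks the 13 lists that passed camera with the preset correlation; none passed with an estimated correlation.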

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

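Chosen after the data were seen were the replicate block combined with choices other than the length correction, edgeR's camera on z-scores, the GC correction, and the share of calls kept after the length correction. The count of 0 changed genes held under RLE, library-size and upper-quartile scaling, limma-voom, no filter, a filter of at least 1 CPM, the length correction and a log2 fold change of at least 1. DESeq2 called 69 genes (49 higher, 20 lower) and edgeR's likelihood ratio test 48 (35 higher, 13 lower), and the cause was not tested. Without each library in turn the count ranged from 0 to 26 (0 to 19 higher, 0 to 7 lower), highest without shEZH2 replicate 2. EZH2's log2 fold change ranged from -1.76 to -1.41 in those fits, and passed the threshold at -1.58 with DESeq2 (adjusted p = 0.00066) and -1.57 with the likelihood ratio test (adjusted p = 0.0089); its adjusted p reached 0.9999 elsewhere. GREB1 ranged from -1.78 to 3.20, ESR1 from -0.85 to 0.87 and EEF1A1 from -0.57 to 0.45 with a library left out. Such fits leave the replicate numbers unequal between the groups, so these ranges can follow number. ESR1 was 566 and 569 CPM in the replicate 1 libraries and 216 and 219 CPM in the replicate 2 libraries. Its within-number log2 ratios were 0.01 and 0.03. ESR1 was -0.0020 without a filter and -0.0081 with the length correction, and the cause was not tested. The median of the E2F list ranged from -0.77 to -0.011 with a library left out. Without shCtrl replicate 1, where it was -0.011, its test pointed higher, which can follow number as well. The number of called lists, 13, became 0 with an estimated correlation or fry, was 13 with RLE, library size and z-scores and 16 with at least 1 CPM, and ranged from 7 to 12 with a library left out. Of the 13, 5 and 8 kept their call without shCtrl replicates 1 and 2, and 6 and 8 without shEZH2 replicates 1 and 2.

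With 2 pairs and no label that says what a replicate number marks, pairing was not established. Deviations of same-numbered libraries from their group means correlated across genes (0.72). With the number as a replicate block, edgeR's quasi-likelihood test called 1399 genes (779 higher, 620 lower), and 1691 (883 higher, 808 lower) with the length correction as well. EZH2 was -1.58 (adjusted p = 3.1e-05) and -1.59 (adjusted p = 5.1e-06) in these fits. All 69 DESeq2 and all 48 likelihood ratio calls were among the 1399, in the same direction, as were all 20 genes taken by size. The block left 1 residual degree of freedom, and its count ranged from 552 to 1691 under the other scalings, tests, filters and the length correction. With a log2 fold change of at least 1 it was 487. It called 11 of the 13 lists, losing DNA methylation (adjusted p = 0.060) and WNT, NOTCH and hedgehog (0.064), and 0 lists with an estimated correlation or fry. Leaving out a library leaves no residual degree of freedom with the block. Of the 1399 calls, 99.7% were kept after the length correction. Of the 1349 calls with a GC value, 95.6% were kept after a GC correction. These shares argue against length or GC as the whole cause. Of 1382 calls placed on a chromosome, 1.09% lay in 25-gene windows with log2 medians past 0.328. Smaller copy-number drift stays open.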

Other observations

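The tests of other cells, scaling and a single pair of libraries for the interferon list were chosen after the result was seen, and so were the genes named in this part. Libraries numbered 1 and 2 differed in many genes. In a fit with group and number, edgeR's quasi-likelihood test called 4643 genes between the numbers, 2280 higher and 2363 lower in replicate 2. The thioredoxin inhibitor TXNIP was 511 and 561 CPM in the replicate 1 libraries and 8.57 and 9.83 CPM in the replicate 2 libraries. Asparagine synthetase ASNS was 57.3 and 37.7 CPM against 482 and 410 CPM, and the cystine transporter SLC7A11 was 22.7 and 6.99 CPM against 212 and 110 CPM. MYC was 34.7 and 19.6 CPM against 180 and 127 CPM, and the progesterone receptor PGR 17.6 and 6.33 CPM against 82.1 and 47.0 CPM (shCtrl, then shEZH2, in each pair). In the list tests between numbers 9 of 33 lists passed with the preset correlation. Ribosomal proteins were higher in replicate 2 (36 called higher and 0 lower of 50, camera adjusted p = 1.1e-08), and so were p53 targets (18 higher and 0 lower of 30, camera adjusted p = 3.0e-06), the unfolded protein and integrated stress response list (15 called higher and 2 lower of 26, camera adjusted p = 0.0002) and genes induced by estrogen (20 higher and 4 lower of 46, camera adjusted p = 0.00028). Lower in replicate 2 were E2F targets (0 called higher and 19 lower of 37, camera adjusted p = 0.00028), the interferon response (1 and 17 of 43, 0.00055) and antigen presentation (0 and 8 of 19, 0.0058). Bivalent regulators (1 and 10 of 40, 0.019) and mitosis (2 and 9 of 38, 0.021) were lower too. With an estimated correlation none of the 9 passed (camera adjusted p = 0.87), but that test had 1 residual degree of freedom and could hardly pass any list. The interferon, antigen presentation, mitosis, E2F and p53 lists are also among those called between shEZH2 and shCtrl.

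For the difference between replicate numbers, thinning all libraries to the smallest total kept 95.8% of the calls, which argues against sequencing depth as the whole cause. A length correction kept 82.1%, and a GC correction kept 64.8% of the 4383 calls, out of 4643, that had a GC value, so part of the difference may follow gene length or GC content. The labels do not say what the numbers mark, and no biological explanation was tested.

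For the rise of the interferon list, leukocyte and endothelial markers were summed, leaving out CD68 and LYZ, which the line expresses. The sum of the 19 markers used was at most 0.873 CPM higher in shEZH2 than in shCtrl within a number. This argues against such cells in the shEZH2 cultures. The lower of the interferon list's medians within a number was 0.645, so a single pair of libraries does not account for its rise. The list's median log2 fold change was at least 0.93 under 4 scalings, but these moved it by only 0.021, so they decide nothing about scaling. A response to EZH2 depletion, a response to the shRNA vector or its sequence, and drift between stable lines all stay open. None was tested, because each group carries its own construct.

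SRM had 2364 and 2372 counts in shCtrl and 448 and 471 in shEZH2, a log2 fold change of -2.32 ± 0.23 (SE), beside -1.57 ± 0.26 for EZH2; the difference between them was not tested.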
